A study of Mus spretus with 12 samples.

How the data were processed

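Total RNA of 12 liver samples labelled as 3 groups of 4 was measured on one-colour Agilent arrays with the dye Cy3, per the labels. Per the labels' protocols, RNA was taken from liver with a column kit that includes a DNase step. The scanner files give an intensity for each spot, and per the file headers the processed signal had been corrected by spatial and multiplicative detrending before it was deposited. The submitters' processing notes name Agilent Feature Extraction 11.5.1.1, RMA and limma, with no role or order. A value table of the same arrays was deposited by the authors as well. Its log2 scale was found by setting each column of the deposited table against the log2 processed signal of its array, with a correlation of 0.9949 to 0.9964 across probes, and its column medians of 5.3243 to 5.3479 were nearly alike, as after quantile normalisation. The exact steps behind that table are not given in the sources used here. It served as an alternative source of values.

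The values used throughout are log2 of the processed signal minus the log2 75th percentile of the array over the spots that are not controls. Of 62976 spots per array, 3671 control spots were left out, and so were spots marked as outliers by the scanner software (102 to 177 per array). Spots of a probe printed several times were averaged. Of 56605 probes, 27098 were well above background on all arrays of at least 1 group and were kept. Each of the 18677 genes was represented by its brightest kept probe. A single probe was kept for 12574 genes and several for 6103. Gene names and mm9 coordinates are those in the scanner files, and a named gene's probe is the one its coordinates describe; names can be old. The probes were designed for the laboratory mouse, and mismatches with Mus spretus were not checked. A mismatch would be the same in all groups, but may alter the size of a change. The choice of the brightest probe, the list tests and the marker means do set probes beside each other. A reference genome was not used here.

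Genes were tested with limma 3.58.1 (R 4.3.3, with the files read by data.table, version 1.17.8) in 1 fit over the 12 arrays with the group as the only term, which left 9 residual degrees of freedom, followed by eBayes and Benjamini-Hochberg adjustment over the 18677 genes. A gene was called at an adjusted p under 0.05. The words rose, fell, higher and lower with a fold or a count refer to called genes. Where a gene was not well above background on any array of the dimmer group, its change is given as at least a certain fold: the mean of the brighter group over the mean, per array, of the higher of the probe's own value and the lowest value among probes well above background (the floor). Means of marker lists take values under the floor at the floor. The 49 lists, 33 of pathways and 16 of cell types, were tested as 1 family per comparison with camera at its preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. With the estimated correlation 5, 9 and 10 lists were called in DDE against control, DDE_PXM against DDE and DDE_PXM against control, where camera with the preset called 20, 23 and 24. A further 5 marker lists were added after seeing the data and have counts and medians but no list test.

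The groups, the tests, the 49 lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule takes, for each comparison, the 6 largest called rises and falls without overlap between the groups, up to 4 members with the smallest p of each list that was called or had called members, and genes to be named whatever their values: Cyp2b10, Cyp3a11, Cyp2c29, Cyp1a1, Cyp1a2, Cyp4a14, Cyp7a1, Nqo1, Gclc, Hmox1, Saa1, Cdkn1a, Tnf, Scd1 and Mup20. Predicted genes without a symbol of their own were skipped. After the data were seen, the 6 largest changes among genes well above background on all arrays were added to the rule, because many of the first were bounds. The text names only some of the genes the rule gives, and these were chosen after their values were seen. Some genes the rule gives are not reported here.

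The arrays lay on 5 slides, and each slide was its own scan pass, so slide and scan could be entered as a single block. Slides held 2 or 3 groups, and changes were also computed within each. Alternatives were quantile normalisation, normexp background correction with an offset of 50, both together (called the RMA-like setting), median centring, the deposited values, no filter or a stricter filter on dim probes, the mean of a gene's probes, moderation with a trend, array weights, only the groups compared in the fit, the replicate number or the slide as a block, outlier spots kept, and each array left out in turn. The gene fit was tested on simulated data: of 50 genes each changed by 0.25, 0.5, 1 and 2 on the log2 scale in DDE against control among 18677 genes, 14%, 66%, 92% and 100% were called, with 4 unchanged genes called.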

Results

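Liver gene expression was measured in male mice of the wild-derived inbred strain SPRET/EiJ (Mus spretus). Per the labels, the mice were 20 months old at the start and 22 months old at sampling, after 60 days of feeding. The series has 3 groups of 4 one-colour Agilent arrays. The control group ate a standard rodent diet with corn oil. A further group, called DDE here, ate the same diet with 450 mg/kg of p,p'-DDE, the persistent breakdown product of the insecticide DDT. The last group, called DDE_PXM, ate the p,p'-DDE diet and drank water with Pedro Ximenez grape must. That water held polyphenols at 85 mg/L and sugar, equal parts of glucose and fructose, at 31 g/L. The title of the series speaks of a protective effect of the must against liver injury by p,p'-DDE, so the arrays address what p,p'-DDE changed and how the must altered that.

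Each array held 59305 spots other than controls, of which between 50.12% and 52.01% were well above background, and no such spot was saturated on any array. The 75th percentile of the processed signal, to which each array was scaled, was 535.1 ± 32.2 in control, 610.8 ± 46.9 in DDE and 702.2 ± 7.62 in DDE_PXM (mean ± SD, n = 4 arrays). The number of arrays limits the precision. Below, the range after a list's median covers the 5 other scalings (quantile normalisation, normexp, the RMA-like setting, median centring and the deposited values), and is given where one of them moved the median by over 1.5 times. After the filter, 18677 genes were tested. The 3 groups separated fully on the first principal component, which held 62.1% of the variance, with control between -51.78 and -47.13, DDE between -0.896 and 3.432 and DDE_PXM between 44.62 and 51.59.

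Arrays within a group differed little. The median SD within groups was 0.109 on the log2 scale over the tested genes, and 0.0799 over the 9930 tested genes above the 75th percentile. For 291 bright probes printed 10 times on every array, a single spot varied between arrays of a group by an SD of 0.0778 (median), against 0.048 between spots of 1 array. The labels number the arrays of a group as replicates, and the design text names 4 mice for the control and for the must group without saying whether RNA was pooled. All p-values here therefore measure only the spread between arrays, which may be technical, and sizes of change say more than counts of genes.

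The first comparison, of DDE with control, asked what p,p'-DDE in the diet changed in the liver. Cyp2b10, a cytochrome P450 that the nuclear receptor CAR induces, rose 82-fold, from 2.55 ± 0.055 in control to 8.91 ± 0.064 in DDE (log2 relative to the 75th percentile, mean ± SD, n = 4 arrays each). Of 36 tested targets of CAR and PXR, the receptors that switch on drug metabolism, 33 rose and 1 fell, with a median log2 change of 0.956 (adjusted p = 9.78e-22). Star, which carries cholesterol into mitochondria for steroid synthesis, was 42.4-fold lower and Cyp11b1, an enzyme of the adrenal cortex, at least 29.3-fold lower, whereas the list of androgen and steroid metabolism was not called (10 higher and 10 lower of 26, or 11 and 11 adjusted over the list alone, adjusted p = 0.911). All 12 markers of skeletal muscle fell, as did most of those of adipocytes and lymphocytes, whose lists were not called with an estimated correlation (adjusted p = 0.0672 to 0.0845), while the mean of the hepatocyte markers was 7.34 ± 0.024 in control and 7.31 ± 0.098 in DDE.

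The probe of Cyp2b10 lies on chromosome 7 at 26711522 to 26711581 of mm9, and its log2 change was 6.36 ± 0.044 (SE, adjusted p = 1.9e-15). Cyp2b9, of the same subfamily, rose 30.4-fold, and Cyp2c38 rose 13.6-fold. Cyp2c65 rose at least 22.9-fold and Cyp2c66 at least 12.1-fold, since both were not well above background on any control array. Members of the CAR and PXR list that rose also included Cyp2c37 (8.33-fold), Cyp2c55 (8.32-fold), Cyp2c50 (4.83-fold) and the efflux transporter Abcc3 (3.07-fold). Cyp3a11, the usual marker of PXR, rose 1.65-fold and Cyp2c29 rose 3.07-fold. Outside the list, Kctd13, an adaptor of a ubiquitin ligase, rose 51.3-fold, from 0.01 ± 0.091 to 5.69 ± 0.099. Chil1, a chitinase-like protein, rose 53-fold, and the protease inhibitor A2m rose 9.94-fold.

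**Figure D1:**
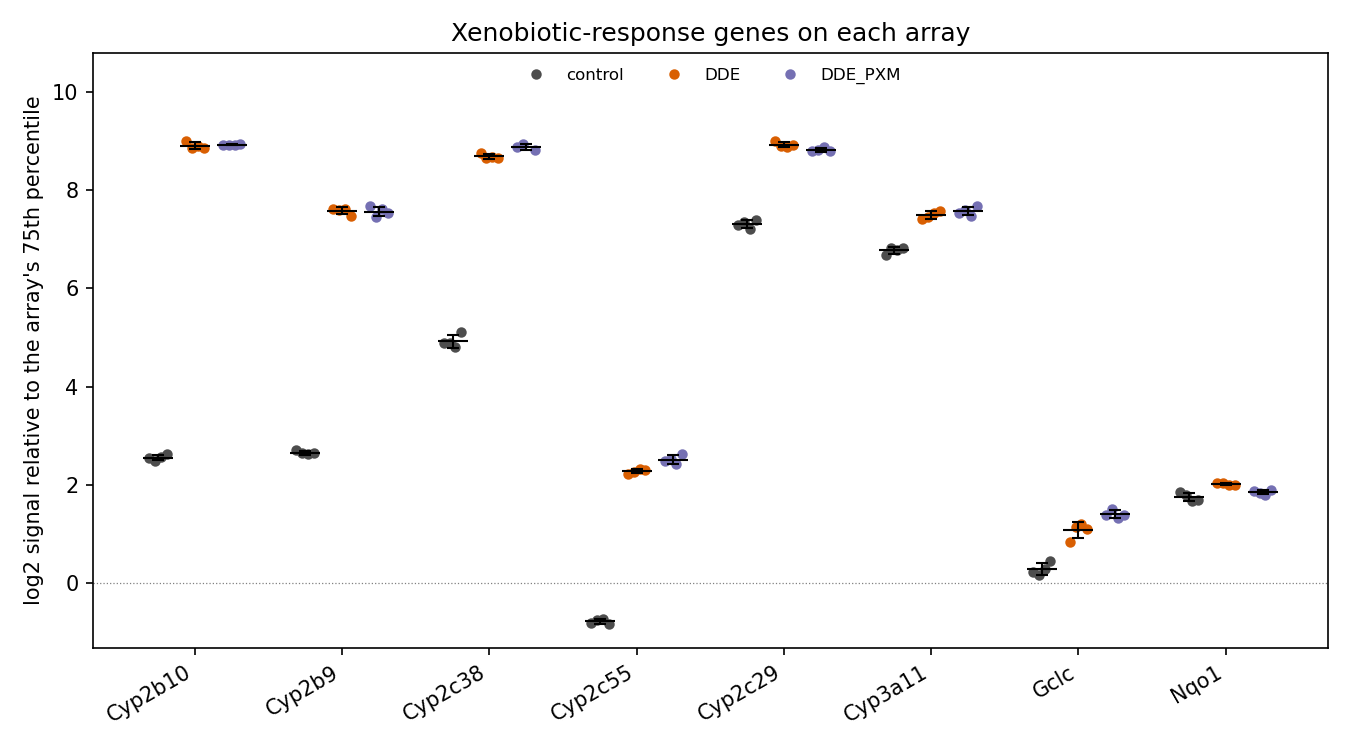
Log2 signal relative to the 75th percentile of the array (vertical axis) for 8 genes of xenobiotic and antioxidant metabolism (horizontal axis) in control, DDE and DDE_PXM; each dot is 1 array and each bar the mean ± SD of a group. Cyp2b10 lies at 2.55 in control, 8.91 in DDE and 8.93 in DDE_PXM.

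Enzymes that conjugate or reduce foreign compounds rose with them. Of 28 targets of NRF2 and genes of glutathione synthesis, 21 rose and 1 fell (median 0.446, range 0.443 to 0.677, adjusted p = 3.39e-08), among them Gclm (2.81-fold), Gclc (1.73-fold) and Gsr (1.61-fold). Ugdh, which makes UDP-glucuronic acid, rose 2.01-fold, and the epoxide hydrolase Ephx1 rose 1.85-fold. Among 21 glutathione S-transferases, 15 rose and none fell (median 0.414, range 0.423 to 0.645, adjusted p = 7.37e-07), with Gstm4 up 3.5-fold and Gstm6 up 3.15-fold. Of 20 glucuronosyl- and sulfotransferases, 15 rose and 1 fell, or 15 and 3 when adjusted over the list alone (adjusted p = 3.21e-06 by camera, adjusted p = 0.0845 with an estimated correlation). Ugt2b35 rose 8.98-fold and Ugt2b38 rose 1.97-fold. For the lists named here the counts adjusted over the list alone were equal to those over all genes unless both are given. Cyp1a2, on the lists of CAR and PXR targets and of targets of the receptor AHR, rose 3.6-fold. Cyp1a1, on the AHR list and well above background on 3 of 4 control arrays, had a log2 change of 0.57 (adjusted p = 0.0723, and 0.0105 to 0.201 over 25 alternatives). The AHR list was not called (8 tested, median 0.246, range 0.195 to 0.477, adjusted p = 0.205 by camera). It was called upward without a filter on dim probes (adjusted p = 0.0459). Nqo1 rose 1.2-fold, and Hmox1, which varied widely within groups (SD 1.1 in DDE), was at -0.01 (adjusted p = 0.995). Its control mean is lowered by control replicate 1, at 1.32 against 3.18 to 3.48 on the other control arrays.

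Genes of lipid and amino acid metabolism moved less. Of 36 targets of PPARA and genes of fatty acid oxidation, 16 rose and 6 fell (17 and 7 adjusted over the list alone), with a median of 0.154 (range 0.149 to 0.385) and adjusted p = 0.0357 (adjusted p = 0.183 with an estimated correlation). Vnn1 rose 2.21-fold, Cpt1b fell 2.33-fold and Cyp4a14 fell 2.25-fold. Skeletal muscle markers fell in this comparison too (median -1.37), and whether the fall of Cpt1b arose in liver cells was not tested. Of 28 genes of amino acid breakdown and the urea cycle, 11 rose and 5 fell (adjusted p = 0.0473, and adjusted p = 0.3 with an estimated correlation). Tdo2 was 1.42-fold higher and Oat 2.36-fold lower. Among the genes of fat synthesis Acly fell 1.61-fold and Scd1 fell 1.33-fold, but that list was not called (6 higher and 12 lower of 27, adjusted p = 0.134). Cyp7a1, the first enzyme of bile acid synthesis, was at -0.07 (adjusted p = 0.417) and Mup20 at -0.11 (adjusted p = 0.0945).

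Plasma protein genes rose in part. Of 26 acute-phase genes, 14 rose and 4 fell (median 0.191, range 0.199 to 0.422, adjusted p = 0.00267, and adjusted p = 0.0845 with an estimated correlation), with Orm3 (3.57-fold), Lcn2 (3.43-fold), Il1rn (2.56-fold) and Lbp (2.41-fold) higher. Saa1, the most inducible of them in inflammation, was at -0.05 (adjusted p = 0.432) from a high level of 9.85 ± 0.065 in control. It was called higher with median centring (0.19, adjusted p = 0.0114) and in the deposited values (0.18, adjusted p = 0.00599). Among 35 genes of complement and coagulation, 19 rose and 6 fell, or 19 and 8 adjusted over the list alone (adjusted p = 0.011, and adjusted p = 0.107 with an estimated correlation). C8a rose 1.42-fold, and Cfd, which adipocytes make in bulk, fell 5.71-fold. The inflammatory signal genes Cxcl10 and Ccl2 were 3.5-fold and 2.26-fold higher in a list that was not called (8 higher and 7 lower of 27, or 8 and 8 adjusted over the list alone, adjusted p = 0.288), and Tnf was at 0.04 (adjusted p = 0.76). With median centring Tnf was called at 0.27 (adjusted p = 0.0196). The stress hormone Gdf15 rose 2.95-fold. The collagen gene Col1a1 was 1.92-fold higher in a fibrosis list that was not called (10 higher and 6 lower of 32, adjusted p = 0.207). Cdkn1a, a p53 target, was at -0.09 (adjusted p = 0.483).

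Genes of protein handling moved in blocks. In the unfolded protein response 20 of 30 genes rose and 2 fell (adjusted p = 2.33e-05, and adjusted p = 0.0845 with an estimated correlation), including Atf3 (1.86-fold) and Trib3 (1.84-fold). In the proteasome 21 of 31 rose and none fell (median 0.221, range 0.226 to 0.452, adjusted p = 2.5e-06, and adjusted p = 0.183 with an estimated correlation), with Psmc4 up 1.46-fold. Of 37 ribosomal protein genes, 27 fell and none rose (28 fell adjusted over the list alone), with a median of -0.251 (range -0.256 to -0.0196) and adjusted p = 6.07e-06 (adjusted p = 0.265 with an estimated correlation). Rps3 was 1.37-fold lower and Rps14 1.26-fold lower, the latter uncalled with median centring (log2 -0.11, adjusted p = 0.131, and 6.08e-06 to 0.131 over 26 alternatives). In oxidative phosphorylation 20 of 36 fell and 2 rose (2 and 21 lower adjusted over the list alone), with a median of -0.216 that turned to 0.0153 with median centring (adjusted p = 0.00179, and adjusted p = 0.396 with an estimated correlation). That call was lost with median centring (adjusted p = 0.222), quantile normalisation (adjusted p = 0.123), the RMA-like setting (adjusted p = 0.132) and the deposited values (adjusted p = 0.126). Cox7a2 fell 1.35-fold.

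Markers of several other tissues fell in DDE, while those of pancreatic islets, in a list added after seeing the data, were higher in 5 of 6 and lower in none. Of 12 muscle markers all 12 fell (median -1.37, adjusted p = 1.95e-11), with the fast muscle genes Myl1 and Tnnt3 lower by 2.76-fold and 2.73-fold. Adipocyte markers fell in 7 of 10 and rose in 1 (median -1.66, range -1.64 to -1.04, or -1.28 with dim members at the floor, adjusted p = 8.96e-05, and adjusted p = 0.0845 with an estimated correlation), with Retn lower by 4.13-fold and Adipoq by 4-fold. Pancreatic acinar markers fell in 10 of 12 (median -0.315, range -0.308 to -0.0839, adjusted p = 0.000621, and adjusted p = 0.105 with an estimated correlation), with the lipase Pnlip 1.4-fold lower. Among 6 markers of kidney and adrenal, 1 rose and 4 fell, or 2 and 4 adjusted over the list alone (median -3.27, or -3.09 with dim members at the floor, adjusted p = 0.00135). In a list of adrenal cortex markers that was also added later, 8 of 9 were lower. That list shares Star, Cyp11b1 and Cyp21a1 with the kidney and adrenal list, so its count is not separate support. Hsd3b1 fell 45.1-fold, Cyp21a1 16.3-fold and Cyp11a1 at least 21.3-fold. Other members moved far less from control to DDE: Mc2r from -2.16 to -2.83, Nr5a1 from 0.82 to 0.31 and Mrap from 0.45 to 0.24. Fdx1 was at 7.16 in control and 7.27 in DDE. Mgarp and Chgb, the latter a secretory granule protein, fell at least 32.9-fold and 42.7-fold. Dlk1 fell 8.37-fold. Krt13, a keratin of stratified epithelium, fell by 3.52 ± 0.28 on the log2 scale (SE), Ly6d fell 10.1-fold, and 12 of 14 markers of that epithelium, in another list added later, were lower and 1 higher.

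Markers of Kupffer cells and lymphocytes fell too. Kupffer cell markers fell in 11 of 15 (median -0.257, range -0.319 to -0.0265, adjusted p = 0.00327, and adjusted p = 0.0554 with an estimated correlation), with Marco 1.96-fold and Lyz2 1.39-fold lower. T and NK cell markers fell in 11 of 16 (adjusted p = 0.000306, and adjusted p = 0.0845 with an estimated correlation), with Cd3d 1.95-fold and Lck 1.61-fold lower. Of 9 B cell and plasma cell markers, 7 fell and 1 rose (adjusted p = 0.00228, and adjusted p = 0.0672 with an estimated correlation), with Jchain 3.01-fold and Ms4a1 2.53-fold lower. Among 27 liver genes higher in females, 14 fell and 5 rose (17 and 6 adjusted over the list alone), with adjusted p = 0.0286 (adjusted p = 0.0845 with an estimated correlation). Cyp2a4 and Cyp2b9, of the same list, rose, the former 2.32-fold. The list of liver genes higher in males had a median of -0.074, which turned to between 0.0573 and 0.157 under the other scalings.

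In all, limma called 9402 of 18677 genes between DDE and control, 4482 higher and 4920 lower, with a median fold of 1.29. At least a 2-fold change was seen for 205 of the higher and 568 of the lower genes, against 373 and 390 with median centring, 269 and 473 with quantile normalisation and 268 and 461 in the deposited values. Normexp gave only 93 and 220, and the RMA-like setting 105 and 210. The 4 values of the groups did not overlap for 8663 genes, or 46.4%, where chance gives 2.86%. With each array centred on its median in place of the 75th percentile, 9019 genes were higher and 2078 lower, or 81.3% higher against 47.7%. That scaling moved the median of all genes to 0.207 here, to 0.103 in DDE_PXM against DDE and to 0.317 in DDE_PXM against control, from -0.0239, -0.0402 and -0.0577. Within each of the 3 slides that held both groups, 99% to 99.5% of the called genes kept the sign of the change, and Cyp2b10 changed by 6.31 to 6.42. These arrays also gave the calls, and genes whose groups did not overlap must keep their sign. The share therefore does not test an effect of the slide. Among the lists, amino acid breakdown was not called in 10 of 26 alternatives, among them those without control replicate 1, 2 or 3 (adjusted p = 0.0718, 0.0554 and 0.053) or DDE replicate 1 or 4 (adjusted p = 0.0521 and 0.0524), within a range of 2e-04 to 0.072.

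The second comparison, of DDE_PXM with DDE, asked what the must changed in mice that ate p,p'-DDE. Genes of fat and cholesterol synthesis rose: Acly, which makes the acetyl-CoA for both, was 3.96-fold higher (log2 1.98 ± 0.052 SE, n = 4 arrays each). Acute-phase and neutrophil genes fell, with Saa1 6.72-fold lower (9.81 ± 0.041 in DDE, 7.06 ± 0.05 in DDE_PXM, mean ± SD) and Lcn2, which is on both lists, 7-fold lower. The induced P450 gene Cyp2b10 was at 8.91 ± 0.064 in DDE and 8.93 ± 0.011 in DDE_PXM, a change of 0.02 (adjusted p = 0.729). Among the large rises were genes of the adrenal cortex and the exocrine pancreas, such as Star (87-fold higher) and the lipase Pnlip (7.56-fold higher).

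Of 27 genes of fat synthesis, 19 rose and 2 fell (median 0.512, range 0.546 to 0.77, adjusted p = 9.94e-10). Me1, which supplies NADPH, rose 2.38-fold, Acaca 2.22-fold and Scd1 2.16-fold. Of 24 genes of cholesterol synthesis and uptake, 20 rose and 1 fell, or 21 and 1 adjusted over the list alone (median 0.366, range 0.391 to 0.609, adjusted p = 7.63e-10), among them Lss (1.63-fold). In glycolysis, gluconeogenesis and fructose metabolism 15 of 31 rose and 5 fell (adjusted p = 0.0107, and adjusted p = 0.246 with an estimated correlation). Tkfc, an enzyme of fructose breakdown, was 2.35-fold higher, Pklr 2.32-fold and Gpi1 1.53-fold. The pentose phosphate enzymes G6pdx and Pgd rose 2.55-fold and 1.95-fold. Both belong to the list of NRF2 targets, where 11 of 28 rose and 5 fell, Cbr1 among them by 2.01-fold (adjusted p = 0.0356, and adjusted p = 0.116 with an estimated correlation). That call was lost without DDE replicate 1 (adjusted p = 0.0567, and 0.00028 to 0.057 over 26 alternatives). Targets of PPARA and genes of fatty acid oxidation fell in 21 of 36 and rose in none, or 23 and 1 adjusted over the list alone (median -0.25, range -0.219 to -0.0204, adjusted p = 4.11e-05). Pex11a was 1.97-fold lower, Angptl4 1.81-fold and Acot1 1.75-fold, as was the fasting hormone Fgf21 (1.95-fold). Adipocyte markers rose beside these genes in 6 of 10 and fell in 1 (median 0.838, range 0.415 to 0.981, or 0.682 with dim members at the floor, adjusted p = 0.000639, and adjusted p = 0.13 with an estimated correlation), with Adipoq 3.26-fold higher.

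**Figure D2:**
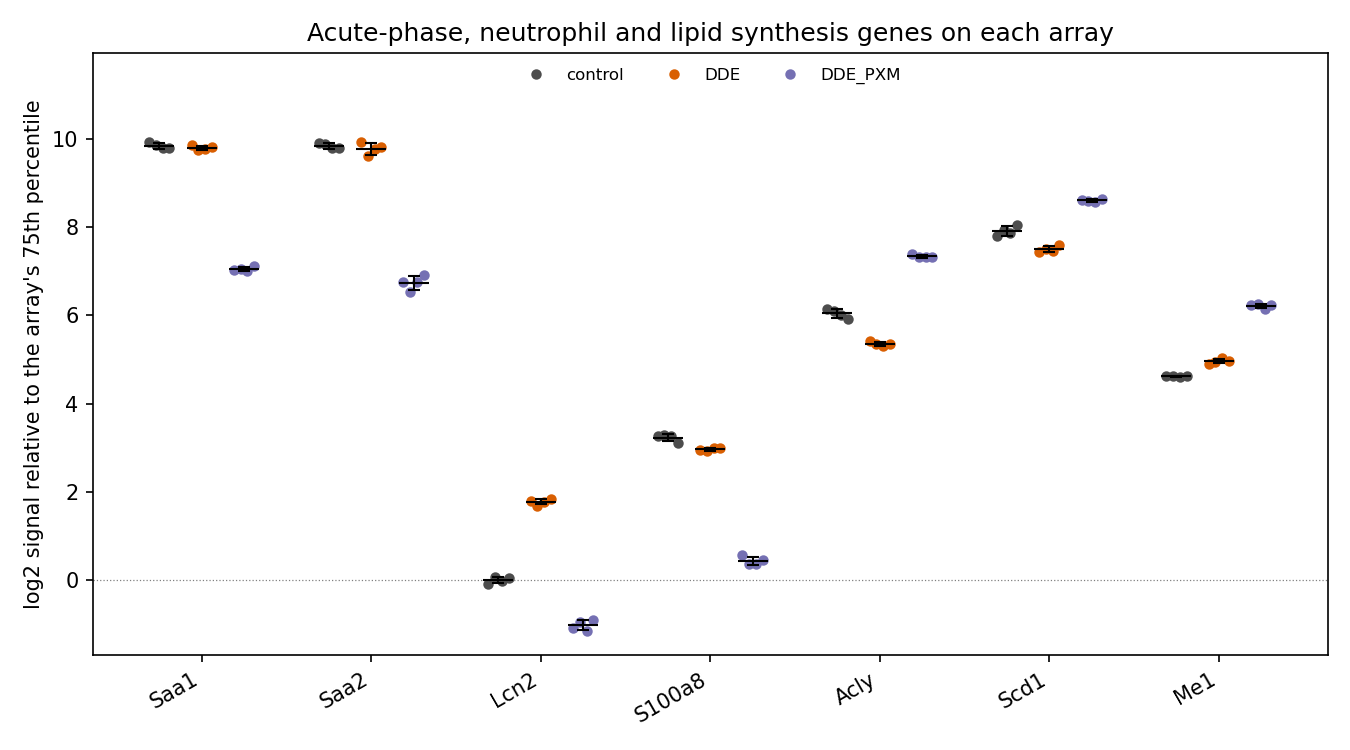
Log2 signal relative to the 75th percentile of the array (vertical axis) for 4 inflammatory and 3 lipid synthesis genes (horizontal axis) in control, DDE and DDE_PXM; each dot is 1 array and each bar the mean ± SD of a group. Saa1 lies at 9.85, 9.81 and 7.06 in the 3 groups, and Acly at 6.05, 5.36 and 7.34.

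Among 26 acute-phase genes, 19 fell and 2 rose (median -0.375, range -0.342 to -0.184, adjusted p = 8.78e-06), with Saa2 8.24-fold and Orm1 2.43-fold lower. Neutrophil markers fell in 7 of 8, or in all 8 adjusted over the list alone (median -1.59, adjusted p = 4.47e-06), with S100a8 5.77-fold and S100a9 5.48-fold lower; the mean of the list was 1.04 ± 0.063 in DDE and -0.51 ± 0.074 in DDE_PXM (SD, n = 4). Prtn3, a protease of neutrophil granules, fell 7.88-fold and A2m fell at least 29.8-fold. Kupffer cell markers fell in 12 of 15 (median -0.358, range -0.339 to -0.215, adjusted p = 0.000448), with Lyz2 1.72-fold and Fcna 1.49-fold lower. Monocyte markers fell in 8 of 12 and rose in 3 (8 and 4 adjusted over the list alone), with Plac8 2.13-fold and S100a4 2.26-fold lower (adjusted p = 0.0332, and adjusted p = 0.158 with an estimated correlation). T and NK cell markers fell in 9 of 16 and rose in 1, or 10 and 1 adjusted over the list alone (adjusted p = 0.0244, and adjusted p = 0.196 with an estimated correlation), with Gzma 2.09-fold and Cd3d 1.5-fold lower. Of 34 interferon-stimulated genes, 22 fell and 3 rose, or 22 and 4 adjusted over the list alone (median -0.305, range -0.278 to -0.162, adjusted p = 0.000211, and adjusted p = 0.101 with an estimated correlation), with Isg15 2.14-fold and Mx1 1.65-fold lower. Erythroid markers fell in 7 of 9 (adjusted p = 0.000448, and adjusted p = 0.158 with an estimated correlation), with Ahsp 4.05-fold and Hbb-b2 2.3-fold lower. Tnf was at -0.09 (adjusted p = 0.479).

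Cell cycle genes and p53 targets fell in DDE_PXM. Of 31 cell cycle genes, 18 fell and none rose (20 fell adjusted over the list alone), with Rrm2 2-fold lower (median -0.359, range -0.319 to -0.188, adjusted p = 0.000282, and adjusted p = 0.0976 with an estimated correlation). Targets of p53 and genes of DNA damage and senescence fell in 15 of 28 and rose in 2, or 16 and 2 adjusted over the list alone (adjusted p = 0.0195, and adjusted p = 0.0697 with an estimated correlation). The cell cycle inhibitors Cdkn2a and Cdkn1a were 2.67-fold and 1.86-fold lower, and Gdf15 1.79-fold. Metallothioneins Mt2 and Mt1, which bind zinc, were 3.57-fold and 2.45-fold lower in a list that was not called (5 higher and 8 lower of 17, adjusted p = 0.51). Hmox1 was at -0.3 (adjusted p = 0.732). The unfolded protein response (14 higher and 6 lower of 30, or 14 and 7 adjusted over the list alone, adjusted p = 0.0722) and the heat shock genes (7 higher and 2 lower of 19, adjusted p = 0.0593) were not called, but were called upward with quantile normalisation (adjusted p = 0.00553 and 0.00488). Of 37 ribosomal protein genes, 34 fell and none rose (median -0.451, range -0.423 to -0.151, adjusted p = 1.85e-10, and adjusted p = 0.131 with an estimated correlation), with Rps27 1.64-fold and Rps14 1.59-fold lower. In oxidative phosphorylation 23 of 36 fell and 3 rose (23 and 5 adjusted over the list alone), Cox7a2 by 1.45-fold, but the median of -0.242 turned to 0.0157 with quantile normalisation, 0.0282 with the RMA-like setting and 0.0339 in the deposited values (adjusted p = 0.0055, and adjusted p = 0.476 with an estimated correlation). With these the call was lost (adjusted p = 0.219, 0.26 and 0.229). Among 20 immediate early genes, 8 rose and 3 fell, or 10 and 3 adjusted over the list alone, with Cyr61 2.67-fold and Nr4a1 2.59-fold higher (adjusted p = 0.0297, and adjusted p = 0.371 with an estimated correlation).

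Liver genes higher in females fell in 17 of 27 and rose in none (median -0.388, range -0.366 to -0.202, adjusted p = 0.000855), with Slc22a26 2.56-fold lower. Those higher in males had a median of -0.132. It turned to between 0.0117 and 0.138 with quantile normalisation, the RMA-like setting, median centring and the deposited values. Genes of the pericentral zone rose in 9 of 20 and fell in 3, with Rnf43 1.38-fold higher (adjusted p = 0.0424, and adjusted p = 0.158 with an estimated correlation). That call was lost without DDE replicate 4 (adjusted p = 0.0619) and without DDE_PXM replicate 3 (adjusted p = 0.0545), within a range of 4e-04 to 0.062 over 26 alternatives. The CAR and PXR list was not called (10 higher and 7 lower of 36, median 0.0824, adjusted p = 0.511), with Gadd45b 2.71-fold, Akr1b7 1.77-fold and Gstt1 1.57-fold lower. It was called upward, however, with quantile normalisation, the RMA-like setting and the deposited values, with medians of 0.252, 0.208 and 0.235 (adjusted p = 0.0144, 0.00999 and 0.00862). Cyp3a11 was at 0.08 (adjusted p = 0.269) and Cyp2c29 at -0.11 (adjusted p = 0.0892). With quantile normalisation, the RMA-like setting and the deposited values, Cyp2b10 was 0.33 to 0.42 and Cyp3a11 0.36 to 0.37 higher, and Cyp2c29 turned to 0.18 to 0.26. Gclc rose 1.25-fold. Cyp1a2 had a change of 0.56 (adjusted p = 0.0254), a call lost without DDE replicate 2 or 4 (adjusted p = 0.0741 and 0.0689) or DDE_PXM replicate 2 or 4 (adjusted p = 0.0756 and 0.0649), with 0.00174 to 0.0756 over 26 alternatives. Cyp7a1 had a change of -0.2 (adjusted p = 0.0284), a call lost without any of DDE replicates 2, 3 and 4 (adjusted p = 0.0767, 0.0751 and 0.0705) or DDE_PXM replicates 2, 3 and 4 (adjusted p = 0.08, 0.0618 and 0.0514), with 0.00156 to 0.517 over 26 alternatives. Nqo1 was at -0.16 (adjusted p = 0.016, and 0.00782 to 0.81 over 26 alternatives), and Mup20 at -0.25 (adjusted p = 0.00171), which turned to 0.09 to 0.12 with quantile normalisation, the RMA-like setting and the deposited values. Cyp4a14 was at 0.17 (adjusted p = 0.304) and Cyp1a1, well above background on 3 of 4 DDE_PXM arrays, at -0.86 (adjusted p = 0.0126).

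Markers of the exocrine pancreas and the adrenal moved far. All 12 acinar markers rose (median 2.52, adjusted p = 4.66e-17), with carboxypeptidase Cpa1 8.89-fold and colipase Clps 6.39-fold higher. The related pancreatic lipase genes Pnliprp2 and Pnliprp1, outside the list, rose 17.1-fold and 10.4-fold. The mean of the acinar markers was 4.93 ± 0.055 in DDE and 7.29 ± 0.014 in DDE_PXM (SD, n = 4). Of 6 kidney and adrenal markers, 5 rose and none fell (median 4.05, or 3.87 with dim members at the floor, adjusted p = 8.03e-07), and in the added adrenal cortex list, which shares Star, Cyp11b1 and Cyp21a1 with it, 8 of 9 rose and 1 fell. Cyp11b1 rose at least 62.6-fold, Mgarp at least 45.1-fold and Cyp11a1 at least 44.6-fold; Hsd3b1 rose 64.7-fold, Cyp21a1 29.1-fold and Akr1cl 10.7-fold. Bcan, a proteoglycan of the brain matrix, rose at least 13.5-fold. Muscle markers fell in 10 of 12 and rose in none (10 and 1 adjusted over the list alone), with Mylpf 1.53-fold and Myl1 1.49-fold lower (median -0.39, range -0.355 to -0.247, adjusted p = 0.00367, and adjusted p = 0.246 with an estimated correlation). Stratified epithelium markers, in the added list, fell in 9 of 14 and rose in 1, with Crct1 at least 5.14-fold and Calm4 at least 3.66-fold lower. Among other large falls were Erich4 (at least 14.1-fold), Ret (at least 5.18-fold), Adora3 (at least 2.68-fold), Lypd8 (8.59-fold) and Rtkn2 (6.15-fold).

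**Figure D3:**
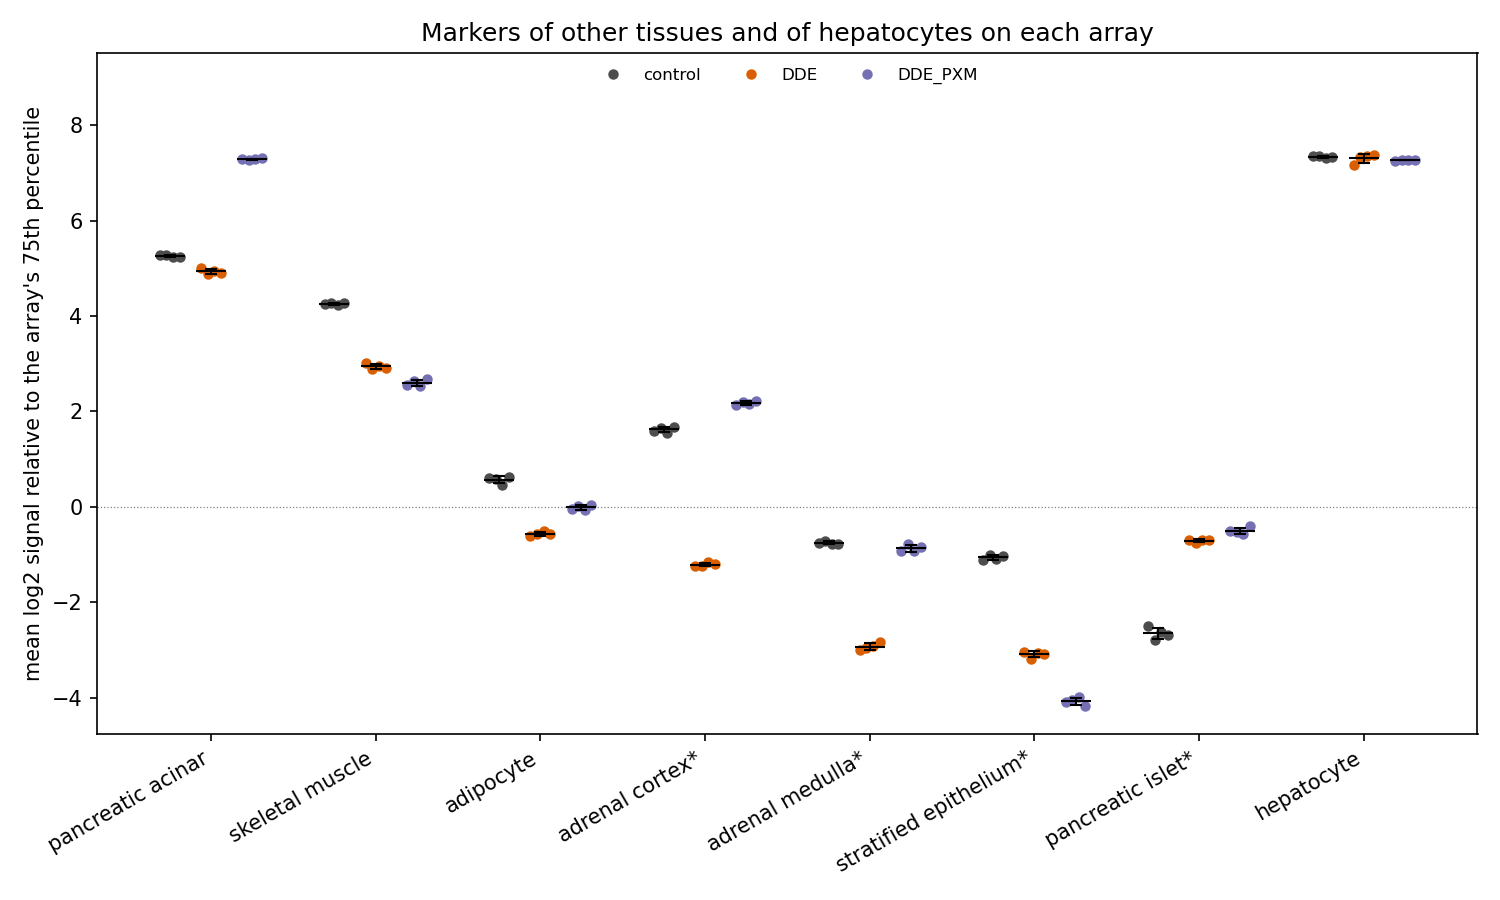
Mean log2 signal, relative to the 75th percentile of the array (vertical axis), over the markers of 8 tissues or cell types, with values under the floor of an array at the floor (horizontal axis), in control, DDE and DDE_PXM; each dot is 1 array, each bar the mean ± SD of a group, and an asterisk marks a list added after seeing the data. Acinar markers lie at 5.26, 4.93 and 7.29 in the 3 groups, adrenal cortex markers at 1.62, -1.21 and 2.17, and hepatocyte markers at 7.34, 7.31 and 7.27.

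In total 9319 genes were called between DDE_PXM and DDE, 3780 higher and 5539 lower, of which 255 and 427 changed at least 2-fold. That balance depended on the scaling, with 308 and 309 for median centring, 290 and 336 for quantile normalisation, 269 and 332 in the deposited values and 143 and 124 for the RMA-like setting. Normexp gave 127 and 160. The groups did not overlap for 8354 genes, or 44.7%, where chance gives 2.86%. Under other scalings the share of higher calls moved from 40.6% to 66.3% with median centring (6475 higher, 3295 lower), 52.2% with quantile normalisation (4790 and 4392), 52.6% with the RMA-like setting (4840 and 4362) and 52.6% in the deposited values (4540 and 4094). Within the 3 slides that held both groups, 98.5% to 99.5% of the called genes kept their sign, and the acinar median was 2.4 to 2.6. That share was largely given beforehand, since the same arrays gave the calls, and does not test an effect of the slide. With the slide as a block the monocyte list was no longer called (adjusted p = 0.0804, and 0.0076 to 0.08 over 26 alternatives).

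The third comparison, of DDE_PXM with control, asked how livers of mice given both p,p'-DDE and must differed from those on the plain diet. The xenobiotic genes stood high, with Cyp2b10 83.2-fold above control (log2 6.38 ± 0.044 SE, n = 4 arrays each) and 30 of 36 CAR and PXR targets higher and 1 lower (median 0.811, adjusted p = 1.48e-11). Cholesterol genes were higher in 21 of 24 and lower in 1 (median 0.54, range 0.589 to 0.914, adjusted p = 6.84e-07). Saa1 was 6.94-fold lower than in control, and markers of Kupffer cells were lower in 14 of 15 and those of T and NK cells in 15 of 16. All 12 acinar markers were higher and all 12 muscle markers lower.

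Kctd13 was 72-fold and Cyp2b9 30.1-fold higher than in control, Cyp2c65 at least 26.8-fold and Cyp2c66 at least 15.3-fold. Chil1 was 23.8-fold, Ugt2b35 11-fold, Cyp2c55 9.8-fold and Cyp2c50 4.7-fold higher. Cyp3a11 was 1.74-fold, Cyp2c29 2.84-fold and Cyp1a2 5.32-fold higher. Of 28 NRF2 targets, 19 rose and 3 fell (median 0.657, range 0.695 to 1.03, adjusted p = 9.26e-06), with Gclm 3.71-fold, Me1 3.03-fold, Gclc 2.16-fold and Gsr 2.09-fold higher. Glutathione S-transferases rose in 14 of 21 and fell in 4 (adjusted p = 0.000467), with Gstm4 5.04-fold and Gstm6 4.48-fold higher. Glucuronosyl- and sulfotransferases rose in 14 of 20 and fell in 4 (adjusted p = 0.00199, and adjusted p = 0.233 with an estimated correlation), with Ugt2b38 2.2-fold higher. Nqo1 was at 0.11 (adjusted p = 0.0695), with adjusted p = 0.0256 without control replicate 1 and 9.06e-06 to 0.455 over 26 alternatives. Hmox1 was at -0.3 (adjusted p = 0.693) and Cyp1a1 at -0.29 (adjusted p = 0.31). The control mean of Hmox1 is lowered by control replicate 1, at 1.32 against 3.18 to 3.48 on the other control arrays.

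Genes of fat synthesis were higher in 19 of 27 and lower in 5 (median 0.661, range 0.702 to 1.04, adjusted p = 5.89e-05), with Mogat1 2.49-fold, Acaca 2.1-fold and Scd1 1.62-fold higher. Dhcr7, the last enzyme of cholesterol synthesis, was 2.41-fold higher. Of 28 genes of amino acid breakdown, 16 rose and 6 fell (adjusted p = 0.0302, and adjusted p = 0.278 with an estimated correlation), with Cbs 1.68-fold higher and Oat 2.89-fold lower. Cyp4a14 was 2.01-fold lower, and Cyp7a1 was at -0.27 (adjusted p = 0.00368), which turned to 0.11 with median centring. Mup20 was at -0.36 (adjusted p = 5.57e-05), but at 0.02 to 0.17 with median centring, quantile normalisation, the RMA-like setting and the deposited values.

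The unfolded protein response was higher in 21 of 30 genes and lower in 3 (median 0.42, range 0.445 to 0.794, adjusted p = 0.000129, and adjusted p = 0.0809 with an estimated correlation); Syvn1, a ubiquitin ligase of the endoplasmic reticulum, rose 2.03-fold and Chac1 fell 3.11-fold. Of 19 heat shock genes, 11 rose and 3 fell, or 12 and 3 adjusted over the list alone (adjusted p = 0.0176, and adjusted p = 0.255 with an estimated correlation), with Hspa1a 2.23-fold higher and Cryab 2.51-fold lower. Skeletal muscle markers were lower here too (median -1.74), and whether the fall of Cryab arose in liver cells was not tested. Proteasome genes rose in 19 of 31 and fell in 5 (adjusted p = 0.00431, and adjusted p = 0.395 with an estimated correlation), with Psmd2 1.72-fold and Psmc4 1.69-fold higher. Ribosomal protein genes fell in 35 of 37 and rose in none (median -0.699, range -0.66 to -0.247, adjusted p = 4.13e-09, and adjusted p = 0.155 with an estimated correlation), with Rps27 2.04-fold and Rps14 2.01-fold lower. In oxidative phosphorylation 25 of 36 fell and 5 rose (median -0.392, range -0.345 to -0.0181, adjusted p = 0.00174, and adjusted p = 0.395 with an estimated correlation), with Cox7a2 1.96-fold lower. That call was lost with quantile normalisation, the RMA-like setting and the deposited values, at medians of -0.0424, -0.105 and -0.0902 (adjusted p = 0.757, 0.742 and 0.777). Genes higher in females were lower in 21 of 27 and higher in 5, or 22 and 5 adjusted over the list alone (median -0.59, range -0.607 to -0.216, adjusted p = 0.00575), with Slc22a26 6.01-fold lower. Genes higher in males had a median of -0.317. It turned to between 0.0313 and 0.212 with quantile normalisation, the RMA-like setting, median centring and the deposited values. Hsd3b5, a liver enzyme of steroid metabolism on the list of genes higher in males, was 18.2-fold lower and Cdkn1a 1.98-fold lower.

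Kupffer cell markers had a median of -0.615 (range -0.647 to -0.241, adjusted p = 0.000173), with Lyz2 2.4-fold and Clec4f 1.52-fold lower. Neutrophil markers fell in 7 of 8 (median -1.22, adjusted p = 0.000467), with S100a9 7.14-fold and S100a8 6.93-fold lower, and Prtn3 was 20.4-fold lower. T and NK cell markers had a median of -0.885 (range -0.76 to -0.413, adjusted p = 0.000467, and adjusted p = 0.0682 with an estimated correlation), with Cd3d 2.92-fold and Lck 1.99-fold lower. Of 9 B cell and plasma cell markers, 7 fell and 1 rose (adjusted p = 0.0169, and adjusted p = 0.092 with an estimated correlation), with Jchain 6.54-fold and Mzb1 2.78-fold lower. Monocyte markers fell in 8 of 12 and rose in 2, or 8 and 3 adjusted over the list alone (adjusted p = 0.0316, and adjusted p = 0.165 with an estimated correlation), with S100a4 4.17-fold and Plac8 3.22-fold lower. Interferon-stimulated genes fell in 21 of 34 and rose in 5, with a median of -0.312 that turned to 0.0619 with median centring (adjusted p = 0.0169, and adjusted p = 0.255 with an estimated correlation); Oas2 was 2.59-fold and Mx1 2.19-fold lower. Cholangiocyte markers rose in 7 of 9 and fell in none, or in 8 adjusted over the list alone (adjusted p = 0.0182, and adjusted p = 0.0809 with an estimated correlation), with Spp1 1.3-fold higher. Acute-phase genes were not called (8 higher and 14 lower of 26, adjusted p = 0.299), and their median of -0.253 turned to between 0.0633 and 0.121 with quantile normalisation, the RMA-like setting, median centring and the deposited values. Tnf was at -0.05 (adjusted p = 0.671), but was called at 0.33 with median centring (adjusted p = 0.0051).

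Among the markers of other tissues, the acinar list had a median of 2.26 (adjusted p = 4.13e-09), with Cpa1 7.58-fold and Clps 5.43-fold higher, and Pnliprp2, outside the list, was 12.4-fold higher. The muscle list had a median of -1.74 (adjusted p = 2.04e-07, and adjusted p = 0.0577 with an estimated correlation), with Myl1 4.12-fold and Tnnt3 3.61-fold lower. Adipocyte markers fell in 8 of 10 and rose in none (adjusted p = 0.0176, and adjusted p = 0.255 with an estimated correlation), with Cfd 2.95-fold and Retn 2.11-fold lower. Kidney and adrenal markers rose in 5 of 6 and fell in none (median 0.912, adjusted p = 0.00442), with Cyp11b1 2.14-fold and Star 2.05-fold higher. Among the large falls were genes of stratified epithelium, with Crct1 at least 36.5-fold, Calm4 at least 26.6-fold, Asprv1 at least 15.8-fold, Krtdap 28.2-fold and Lor 13.6-fold lower; in the added list 13 of 14 were lower and 1 higher. S100a14 and Lce1a1 fell at least 14.5-fold and 13.1-fold, Bpifa5 13.7-fold and Rtkn2 10.5-fold.

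**Figure D4:**
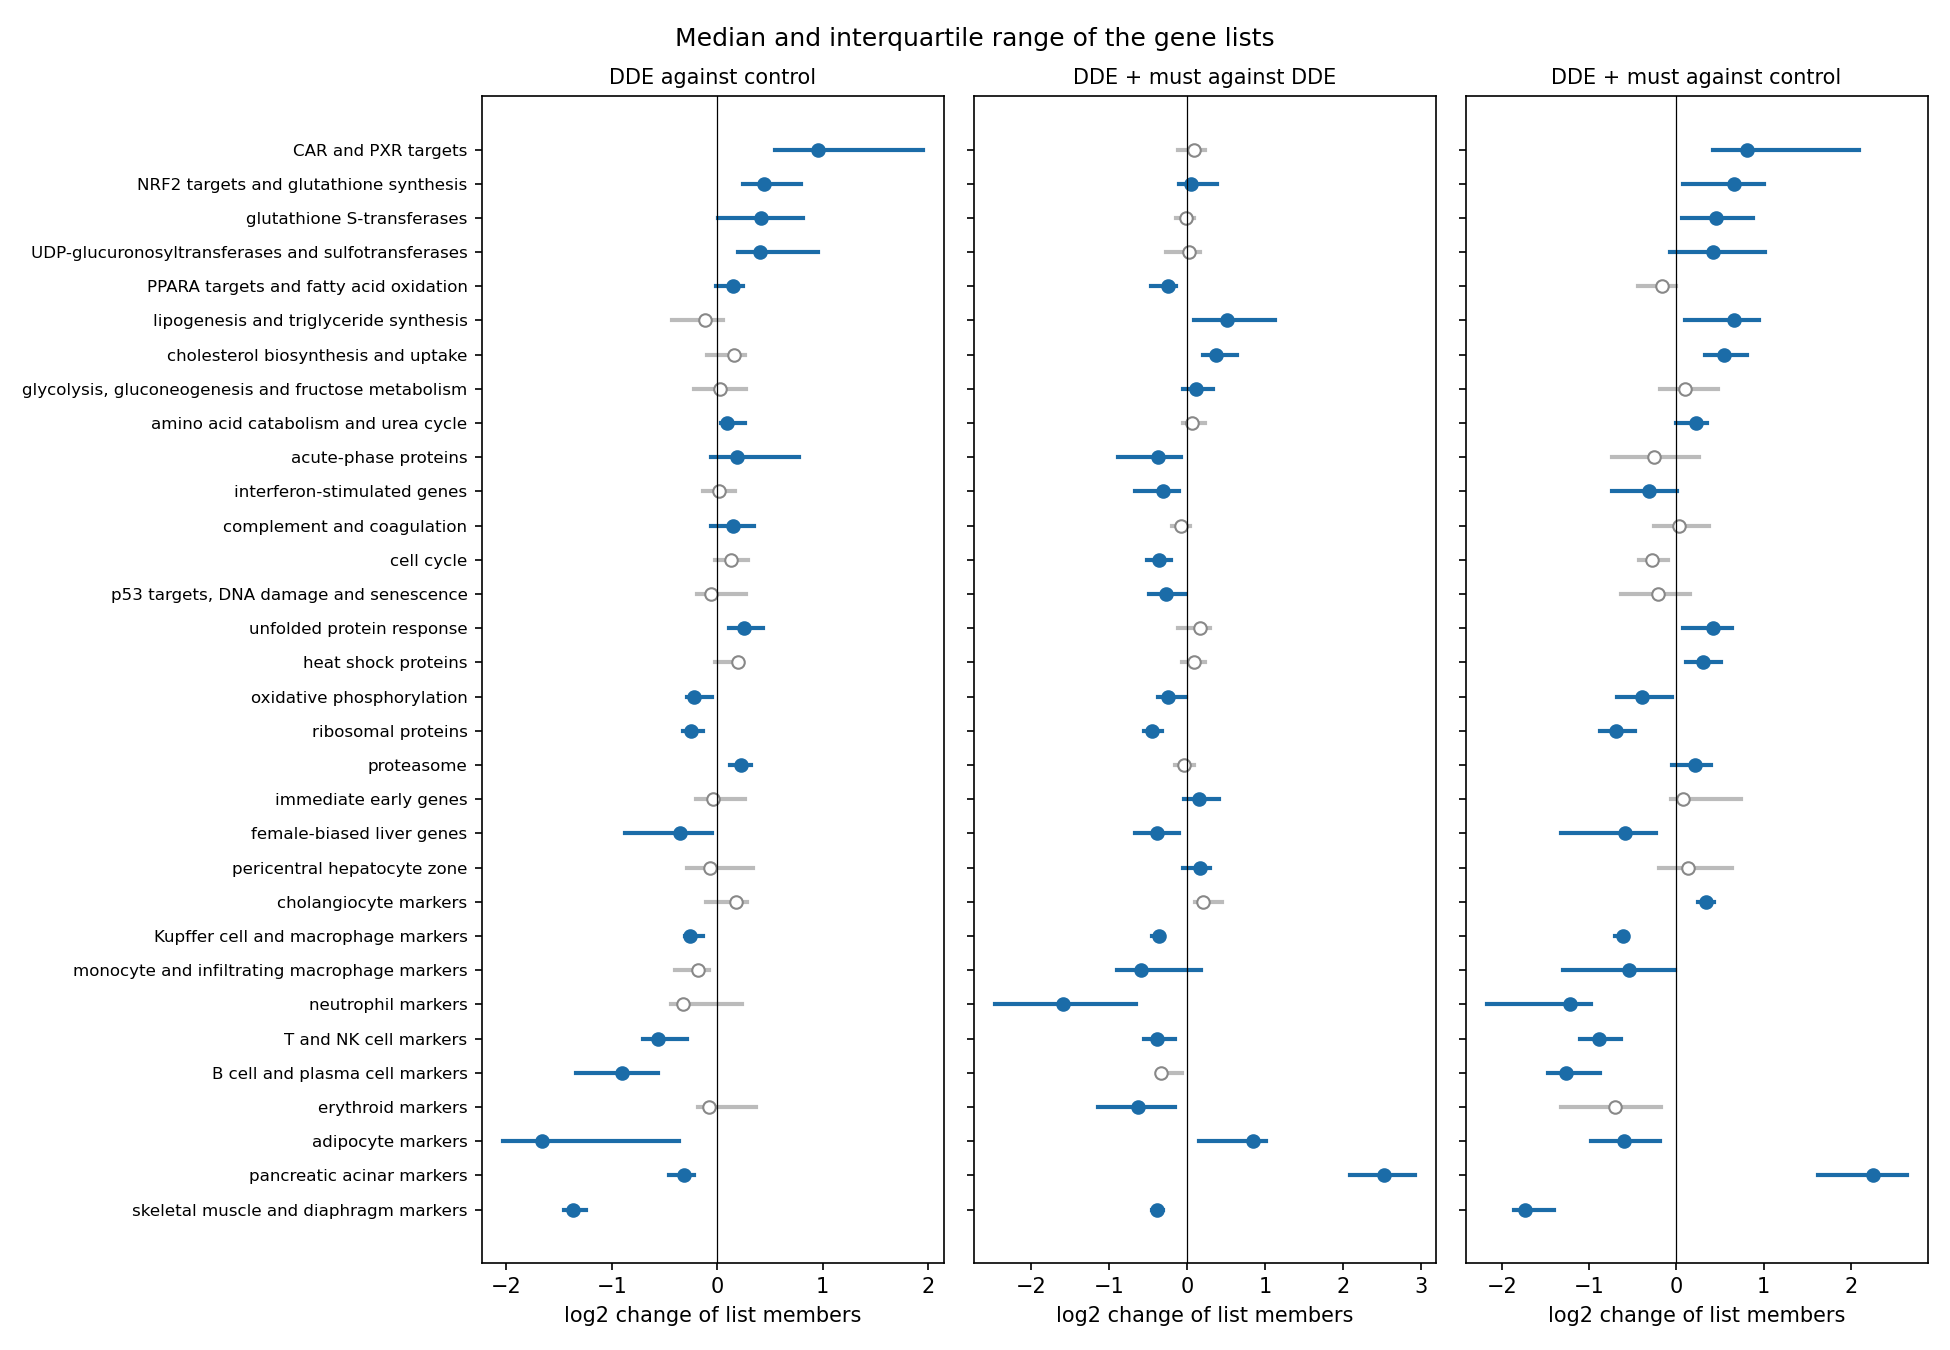
Median log2 change (point) and interquartile range (line) over the tested members of each gene list called in at least 1 comparison, with 1 panel per comparison; filled points mark the comparison in which a list was called, and the kidney and adrenal list is left out. CAR and PXR targets lie at 0.956, 0.0824 and 0.811 in DDE against control, DDE_PXM against DDE and DDE_PXM against control, and the oxidative phosphorylation medians of -0.216 and -0.242 in the first and second turn positive under other scalings, as does that of -0.312 for interferon-stimulated genes in the third.

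Between DDE_PXM and control 13241 genes were called, 5892 higher and 7349 lower, with a median fold of 1.45, and 446 and 1760 of them changed at least 2-fold. The excess of falls turned round with median centring (1618 and 760) and shrank with quantile normalisation (758 and 1217) and in the deposited values (718 and 1155). Both counts were lower with normexp (249 and 857) and the RMA-like setting (365 and 606). The groups did not overlap for 12178 genes, or 65.2%, where chance gives 2.86%. With median centring 10314 were higher and 3802 lower, or 73.1% higher against 44.5%. Within the 3 slides that held both groups, 99.3% to 99.6% of the called genes kept their sign and Cyp2b10 changed by 6.31 to 6.44. Here too the same arrays gave the calls, so the share does not test an effect of the slide. The monocyte list was no longer called with the slide as a block (adjusted p = 0.0561), normexp (adjusted p = 0.0533), no filter on dim probes (adjusted p = 0.0694) or only the groups compared in the fit (adjusted p = 0.0508), within a range of 0.012 to 0.069 over 26 alternatives.

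The changes with DDE and those with the must were then set against each other. Of the 205 genes at least 2-fold higher in DDE, 89 fell, 48 rose further and 68 were not called when the must was given, and 114 stayed at least 2-fold above control. Of the 568 at least 2-fold lower in DDE, 114 rose, 257 fell further and 197 were not called, and 442 stayed at least 2-fold below control. Of all 9402 genes called between DDE and control, 4690 were called with the must in the same direction, 1174 in the opposite one and 3538 were not called. By sign alone, called or not, 25.7% of the 9402 were opposite to the DDE change. Both changes contain the DDE arrays with opposite signs, so this share was also taken among the 18628 genes with values on all arrays, where it was 25.8% of 9377 called. In 20 simulations of unchanged groups the 9377 genes of lowest p had opposite signs in 75.6% (75% to 76.4%). The simulated groups hold no change, so this share and the simulated correlation below show what noise in shared arrays gives alone. They do not show how far shared arrays move these values where changes exceed the noise. With the DDE arrays split between the comparisons, in 6 ways, the share was 24.2% (23.1% to 25.3%). Among genes changed at least 2-fold by DDE it was 36.9%. The correlation of both changes across genes, which are not independent replicates, was 0.0327 against -0.503 simulated and 0.0703 with the split, and the covariance 0.00806 against -0.00928 simulated and 0.0181 with the split.

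**Figure D5:**
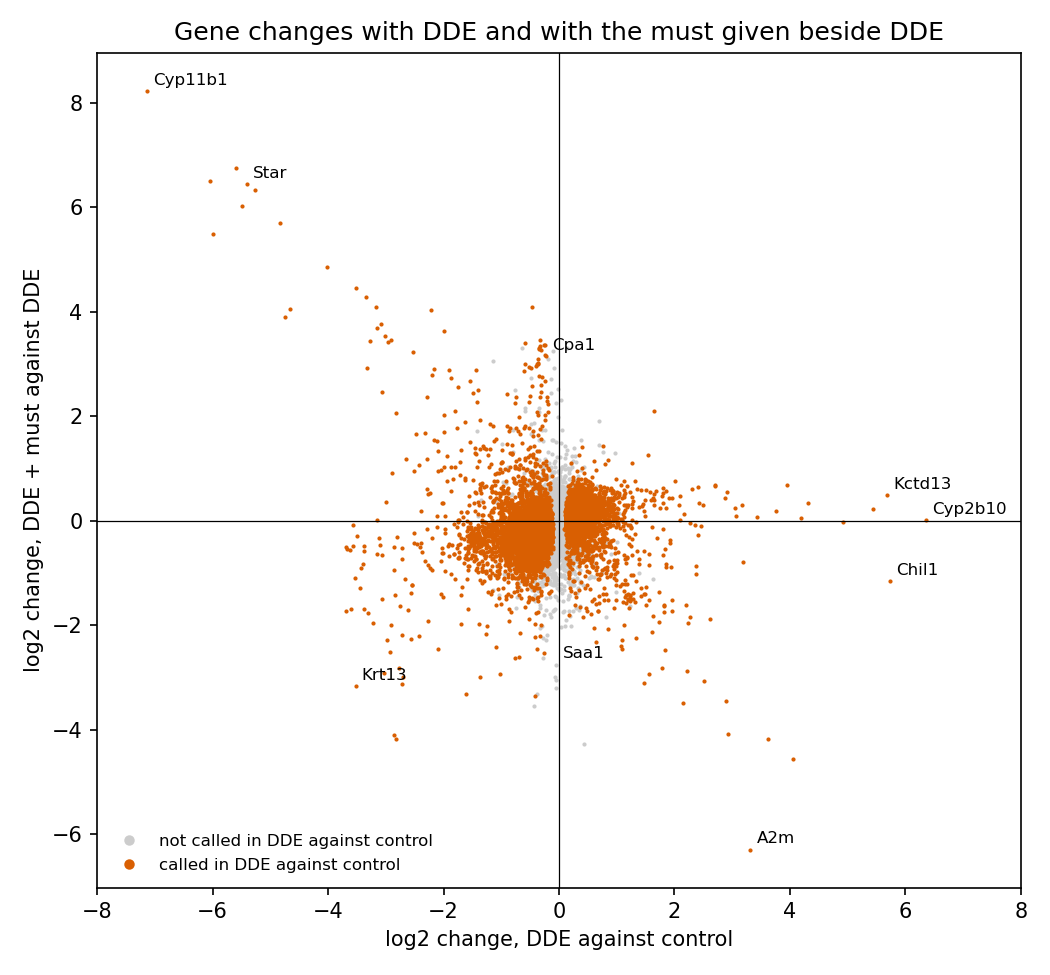
Log2 change in DDE against control (horizontal axis) and in DDE_PXM against DDE (vertical axis); each point is 1 tested gene, and named genes are labelled. Cyp2b10 lies at 6.36 and 0.02, and Star at -5.41 and 6.44.

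Both treated groups shared much of their difference from control. In the comparisons of DDE and of DDE_PXM with control, 3805 genes were higher in both, where independent lists of the same length give 1414, and 4278 were lower in both, where independent lists give 1936. Together 8083 genes were called in the same direction and 358 in opposite directions. Simulated unchanged groups against the same controls gave 0.05 genes on average (0 to 1), and splitting the control arrays between the comparisons gave 6308 (6065 to 6633). The simulated groups hold no change, so nearly no gene is called in them. Their count cannot show what shared controls add to the overlap. The correlation across genes was 0.725, against 0.503 simulated and 0.685 with the split, and the covariance was 0.259 against 0.00928 simulated. The simulated correlation, too, shows noise in shared arrays alone. If the arrays of a group share 1 RNA pool, splitting them does not remove the error they share.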

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

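The genes examined in this part are those named in the text and were chosen after their values were seen, whereas the test for a far array was fixed before the data were examined. In each group of 4 arrays, an array was singled out when its gap to the nearest other exceeded the critical value of Dixon's test over the range of the group. Of 606 sets of 4 values, 29 held such an array, where chance at 1 in 20 gives about 30. All values are log2 relative to the 75th percentile unless said otherwise. No explanation of single arrays was tested.

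DDE replicate 1 was far from the other DDE arrays in 6 sets. Its mean of the NRF2 list was 4.78 against 4.89 on the others, and its mean of the periportal list 4.94 against 5.24 to 5.25. Its Rps3 stood at 7.09 against 6.85 to 6.87, Cyp7a1 at 2.96 against 3.2 to 3.22, Lypd8 at 2.79 against 2.38 to 2.39 and Ahsp at -1.25 against -1.55 to -1.53. DDE replicate 2 was far in Mx1 (-0.08 against -0.19 to -0.17) and Akr1b7 (4.85 against 4.92 to 4.94). DDE replicate 3 was far in the means of the p53 list (0.47 against 0.51) and the circadian list (1.87 against 1.82 to 1.83), and in Retn (-2.19 against -2.44 to -2.41). DDE replicate 4 was far in Cyp2b9 (7.48 against 7.6 to 7.62) and Cyr61 (-1.8 against -1.91 to -1.9).

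DDE_PXM replicate 1 was far in 5 sets: the mean of the B cell list was -1.62 against -1.99 to -1.98, A2m -5.14 against -6.76 to -6.56, Cox7a2 6.99 against 6.88 to 6.89, Acly 7.4 against 7.32 to 7.33 and Rtkn2 -3.53 against -4.48 to -4.39. DDE_PXM replicate 2 was far in the mean of the fibrosis list (-0.17 against -0.27 to -0.25). DDE_PXM replicate 3 was far in the mean of the CAR and PXR list (4.5 against 4.62 to 4.64), in Vnn1 (1.52 against 1.7 to 1.73) and in Retn (-1.33 against -1.42 to -1.41). DDE_PXM replicate 4 had 177 outlier spots, against 108 to 114 on the other arrays of its group.

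Control replicate 1 was far in Hmox1 (1.32 against 3.18 to 3.48), the widest of the gaps given here, and in Tdo2 (6.43 against 6.49 to 6.5) and Il1rn (-2.41 against -2.09 to -2.04). Control replicate 4 was far in S100a8 (3.11 against 3.26 to 3.28) and Gadd45b (-0.4 against -0.31 to -0.3), and had 102 outlier spots against 130 to 135 on the other control arrays.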

How the results depend on the processing

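No alternative in this part was chosen after seeing the data. The counts of called genes and lists, the share of opposite changes and the overlap kept within 1.5 times of their reported values under all alternatives except those given here. Without a filter on dim probes, 14102 genes were called in DDE_PXM against DDE and 21802 in DDE_PXM against control, 31 lists were called in DDE against control, the share of opposite changes was 17.1% and the overlap 12657 genes; more genes were tested by construction. With at least a 2-fold change required as well, 773, 682 and 2206 genes were called in DDE against control, DDE_PXM against DDE and DDE_PXM against control. In its own fit, normexp called 93 higher and 220 lower, 127 and 160, and 249 and 857, and the RMA-like setting 105 and 210, 143 and 124, and 365 and 606. Camera with an estimated correlation called 5, 9 and 10 lists, and fry, which does not compare a list with other genes, 42, 41 and 46.

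With each array left out in turn, the genes called numbered 8478 to 9443 in DDE against control, 8215 to 9387 in DDE_PXM against DDE and 12598 to 13516 in DDE_PXM against control, and the lists 19 to 21, 22 to 24 and 24 to 25. The share of opposite changes was 24.6% to 27.1% and the overlap 7308 to 8031 genes.

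With the replicate number as a block, 8782, 8599 and 12936 genes and 21, 23 and 24 lists were called, the share of opposite changes was 25.4% and the overlap 7578. In DDE_PXM against DDE, Cyp1a2 (adjusted p = 0.0575) and Cyp7a1 (adjusted p = 0.0673) were not called with this block. The numbers do not pair the arrays: over 12 pairs of arrays with the same number, deviations from the group means correlated with a median of -0.0157 (-0.368 to 0.132), 1 pair over 0.1, and 0 arrays were closest to their own number. Arrays of different groups on the same slide were more alike, with a median of 0.189 over 9 pairs (-0.114 to 0.347), 5 of them over 0.1. Over 28 pairs that shared neither it was -0.0114 (-0.288 to 0.203). The deviations thus carry some effect of slide or scan. With the slide as a block, which is also the scan block, 9658, 9207 and 13257 genes and 21, 22 and 24 lists were called, the share was 26% and the overlap 8289. In that fit, in DDE_PXM against DDE, Cyp7a1 (adjusted p = 0.0587) and Nqo1 (adjusted p = 0.0637) were not called, and Cyp1a1 in DDE against control was (adjusted p = 0.02).

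Of 6236 alternative values of the 241 named gene values, 6174 kept their direction and side of the threshold, 21 lost a call, 27 gained one and 14 reversed. In DDE_PXM against DDE, Cyp2c29 turned to 0.26 with quantile normalisation, 0.18 with the RMA-like setting and 0.26 in the deposited values, and Mup20 to 0.12, 0.09 and 0.1. In DDE_PXM against control Mup20 turned to 0.15, 0.14 and 0.17 in these and to 0.02 with median centring. Median centring also turned Cyp7a1 to 0.11 and Tnf to 0.33 in DDE_PXM against control and, in DDE against control, Saa1 to 0.19, the last being 0.18 in the deposited values. The cause was not tested.

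Of the lists called, some lost their call under a change of scaling, filter or fit, with the range of adjusted p over 26 alternatives given for each. In DDE against control these were amino acid breakdown (2e-04 to 0.072), PPARA targets (7.3e-05 to 0.058), oxidative phosphorylation (0.00057 to 0.22) and genes higher in females (0.0024 to 0.081). In DDE_PXM against DDE they were oxidative phosphorylation (0.0039 to 0.26), immediate early genes (3e-04 to 0.054), pericentral genes (4e-04 to 0.062), monocyte markers (0.0076 to 0.08) and T and NK cell markers (0.0085 to 0.088). In DDE_PXM against control they were interferon-stimulated genes (0.013 to 0.085), oxidative phosphorylation (0.0011 to 0.78), monocyte markers (0.012 to 0.069) and cholangiocyte markers (0.00036 to 0.078). Other lists gained a call, among them the following. In DDE_PXM against DDE, quantile normalisation, the RMA-like setting and the deposited values each called CAR and PXR targets, glutathione S-transferases, glucuronosyl- and sulfotransferases, proteasome, complement, bile acid, amino acid, periportal, cholangiocyte, unfolded protein and heat shock lists upward and cytokines downward, and in DDE_PXM against control complement, periportal and glycolysis lists and in DDE against control the periportal list upward. Calls that hung on single arrays: without DDE replicate 1, Cyp1a1 (0.73, adjusted p = 0.0313) and Mup20 (-0.14, adjusted p = 0.0341) were called in DDE against control and Cyp4a14 (0.3, adjusted p = 0.0184) in DDE_PXM against DDE, and without DDE_PXM replicate 4, Cyp1a1 (0.57, adjusted p = 0.0447) in DDE against control; over all alternatives these p ranged from 0.0105 to 0.201, 0.0195 to 0.874 and 0.0184 to 0.738.

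Between 50.12% and 52.01% of spots were well above background, so changes of dim genes are given as bounds, and genes dim in all groups were not tested.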

Other observations

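The tests of the tissue markers were chosen only after the results were seen, as was the use of the planned scalings and split arrays for the direction of change. Among 9 markers of the adrenal cortex, group means were 1.62 ± 0.054 in control, -1.21 ± 0.035 in DDE and 2.17 ± 0.04 in DDE_PXM (log2, SD, n = 4 arrays; values under the floor of an array are taken at the floor, so that low means are upper bounds). For 7 markers of the adrenal medulla they were -0.75 ± 0.03, -2.93 ± 0.07 and -0.86 ± 0.069, and in DDE_PXM against control 2 of these were higher and 5 lower, where 6 cortex markers were higher and none lower. Markers of pancreatic islets took another course, at -2.65 ± 0.12, -0.71 ± 0.033 and -0.5 ± 0.071, with insulin gene Ins1 at 0.06 ± 0.12, 2.36 ± 0.11 and 2.97 ± 0.11. Of 6 tested islet markers, 5 were higher in DDE than in control and 6 higher in DDE_PXM than in control, whereas the acinar markers of the same organ fell in DDE. Markers of stratified epithelium fell from -1.05 ± 0.054 to at most -3.09 ± 0.065 and -4.07 ± 0.078, with 4 of 14 not well above background on any DDE array and 9 on any DDE_PXM array. Among 5 lung markers, 3 fell and none rose in DDE against control, and 2 rose and 2 fell in each of the other comparisons.

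Each comparison was set against the 35 splits of its 8 arrays into 4 and 4. The real split called 9402, 9319 and 13241 genes, the highest of the other splits called 1 gene in each comparison, and 1 of 35 splits, the real one, gave as many in each. The arrays thus separate by group label, as the principal components had already shown, and mixed splits put the group difference into the spread. If the arrays of a group share 1 RNA pool, the splits cannot tell a treatment effect from a chance difference between pools. They say nothing about how many animals the arrays stand for.

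Arrays within a group differed little in genes that vary between animals. Over 64 genes of the acute-phase, immediate early and circadian lists, which respond to stress, feeding or the time of day, the SD within groups was 0.995 times that of genes of the same brightness (median over genes of the ratio; the separate medians were 0.0882 and 0.0788). This ratio is consistent with arrays of a group that carry the same or pooled RNA. Animals kept and sampled very uniformly may give a low ratio too. Yet marker means of other tissues were also nearly equal within groups. Acinar means were 5.26 ± 0.029, 4.93 ± 0.055 and 7.29 ± 0.014 in control, DDE and DDE_PXM (SD, n = 4 arrays). Muscle means were 4.26 ± 0.019, 2.94 ± 0.06 and 2.6 ± 0.07. If these markers come from tissue taken along with the liver, such equal amounts argue against separately sampled animals. If the liver itself made them, uniform animals stay open as untested. Some values within groups lay further apart than 1 shared RNA would lead one to look for. Hmox1 was at 1.32 on control replicate 1, against 3.18 to 3.48 on the other control arrays. The mean of the periportal list was 4.94 on DDE replicate 1, against 5.24 to 5.25 on the others. Far arrays were seen in 29 of 606 sets, where chance gives about 30, so these values do not decide the question.

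Acinar markers and muscle markers each moved together, whereas islet markers did not follow the acinar ones. All 12 acinar and all 12 muscle markers (12 at least in each list) moved in 1 direction, with acinar changes around 2.52 (interquartile range 0.831) in DDE_PXM against DDE and muscle changes around -1.37 (0.215) in DDE against control, as differing amounts of neighbouring tissue in the samples may give. Scaling is argued against, since the lowest acinar median over the other scalings was 2.52. A lower share of hepatocytes would raise all of them alike, but the acinar and muscle medians lay 2.91 apart in DDE_PXM against DDE. A change of such genes within the liver by the diet or the must stays open as untested.

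For most genes called between DDE and control the must change had the same sign, though 4690 of 9402 were called again in that direction and 1174 in the other. The share of opposite signs was 25.7%, and it reached at most 24.6% under the other scalings (lowest 21.7%) and was 22.2% of 5591 called genes above the 75th percentile, which argues against scaling and dim genes, while the 24.2% with the DDE arrays split decides nothing, since shared arrays push towards opposite signs. Among 503 called members of the pathway lists that are on no fixed cell type list it was 39.2%. Pathway genes that other tissues also express stay among them, so this share cannot decide whether RNA of other cells is the cause. As a hypothesis, the must may add to a response that p,p'-DDE begins for part of the genes, while for others, such as Acly and Lcn2, it moves past control to the other side; a group given must alone, with each mouse on its own array, would test this and would tell it from a difference between RNA pools.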
